A study of Mus musculus with 4 samples.

How the data were processed

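Total RNA of CGR8 embryoid bodies at day 3 or day 10 was hybridised with day 0 RNA on 4 arrays with 2 channels each, per the labels. The deposited table gives 1 value per spot and array, taken here as the log2 ratio of the channels. The base was settled from the values: on the first array, 4.48% of the first 5000 values were ratios of whole numbers with a denominator up to 100 in base 2 (within 5e-05 of a whole number), against 0.820% in base e and 0.940% in base 10. With whole numbers up to 10000, between 59.3% and 62.0% of the values of an array were such ratios to their 9 decimals, against at most 1.70% after a small random shift. The deposited medians were -0.03, -0.03, -0.01 and -0.04, and the share of spots with no value 12.5%, 10.3%, 18.8% and 13.4%. The scanner, software, background treatment, dyes, the channel in the numerator and the rule for missing values are not given in the sources used here. A constant added to the log ratios would have broken the whole-number ratios, so no such centring shows in the values that are ratios of this kind. Whether the channels were corrected for dye bias before the ratio was taken is unknown.

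Spots were named through a probe table taken from the platform's annotation, with symbols looked up by Entrez ID in the RefSeq gene table of GRCm38.p6, which changed 0 symbols. There, 32544 spots had 1 gene symbol and 588 had several, and 12996 spots had no row and are unnamed here. Of the named spots, 480 belonged to 5 accessions spotted 96 times each whose Entrez IDs are not mouse genes. They were taken as controls and left out, a choice made after the data were examined. The 32064 spots kept stand for 14386 genes, with a median of 2 spots per gene, and 400 of them had an Entrez ID that the gene table does not hold.

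Each array was centred on the median of its spots without controls, and the spots of a gene were averaged. A gene was called beyond 2-fold where both technical arrays were at or beyond 1 on the log2 scale on the same side. Genes beyond that limit on opposite sides were counted as a measure of error. For day 10 against day 3, all 4 differences between a day 10 and a day 3 array had to be at or beyond 1 with 1 sign, and the SD combines both pairs of arrays. No significance test was run, because each group is 1 RNA pair. The 24 gene lists were fixed before the data were examined, and the median of each was ranked among 10000 random lists of its size drawn from the measured genes.

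The genes named were chosen by a rule written before the data were examined. It takes the 8 largest and 8 smallest called means at each day (5 and 5 between days), leaving out RIKEN, EST and predicted names and keeping at most 2 members of a family. It adds the 2 called members farthest from 0 of each list and 10 genes followed throughout, of which T was not on a named spot. Gapdh, Tk1, Plvap and Cox7a2 were added after their values were seen.

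Recovered brightness is the log2 geometric mean of the smallest whole numbers whose ratio gives the deposited value. If the channel values were whole numbers it is a lower bound, since a common factor is lost, and it was chosen after the data were examined. Values that are not ratios of whole numbers up to 10000 were given larger numbers and so count as bright. Recovery was tested on pairs drawn up to 10000 alone. The steps were tested on simulated data. With 13707 genes and day 3 noise, 67% of genes changed by 1.5 (log2) and 100% of those changed by 3 were called on the right side, and 79 unchanged genes were called. With 13199 genes and day 10 noise the figures were 63%, 97% and 136. The array noise was spread over all genes at random, which gave 62 genes beyond the limit on opposite sides at day 3 and 137 at day 10. The data had 102 and 195, so 79 and 136 may understate the unchanged genes called. Of simulated lists of 30 genes with no shift, 5.5% lay outside the central 95%.

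The alternatives fixed in advance were no centring, a common spread for all arrays, limits of 1.5-fold and 4-fold, the limit on the mean alone, each spot counted on its own, genes with values on all 4 arrays, ranks, random lists matched on array difference, the spot with the smallest array difference, genes with the smaller array differences, and each array left out in turn. Those added after the data were examined were sets of 25% of the genes by brightness, removal of each array's brightness trend in 50 bins, and random lists matched on brightness in 10 bins. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with plots by matplotlib 3.10.9.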

Results

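Mouse embryonic stem cells of the CGR8 line were left to differentiate as embryoid bodies, the round cell aggregates that form when stem cells are grown in hanging drops. Total RNA of embryoid bodies at day 3 and at day 10 was each hybridised on spotted 2-channel arrays together with RNA of the undifferentiated cells at day 0. The series holds 4 arrays, 2 for day 3 with day 0 and 2 for day 10 with day 0, and the second array of each pair is labelled a technical replicate. The arrays of a pair therefore count as 1 replicate, their SD measures technical error alone, and no p-value is given. Whether the second array is a repeat labelling, a repeat hybridisation or a second scan is not given in the sources used here, so which steps that error covers is unknown. Each array has 46128 spots, of which 40348 and 41386 carried a log2 ratio on the day 3 arrays and 37471 and 39955 on the day 10 arrays. The number of arrays limits the precision of every value. Dyes and the numerator of the ratio are not given in the sources used here, so the sign is the deposited one, and "positive side" and "negative side" do not say which day was higher. The titles of the day 10 arrays read "day0 vs day10", which names day 0 first but does not state the numerator.

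Technical arrays differed more for dim genes than for bright ones. Across the genes with a value on both arrays, Pearson r was 0.271 (Spearman rho 0.335, 13707 genes) for the day 3 pair and 0.215 (rho 0.261, 13199 genes) for the day 10 pair. These correlations run across genes, which are not independent replicates. In the 25% of genes with the highest recovered brightness, a measure chosen after the data were examined, r was 0.755 at day 3 and 0.592 at day 10, and in the dimmest 25% 0.0258 and 0.0394. The SD of 1 array was 0.62 at day 3 and 0.73 at day 10 over all genes, and 0.29 and 0.40 in the brightest 25%. Arrays of different days correlated at r between 0.115 and 0.161, so none ran against another.

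**Figure D1:**
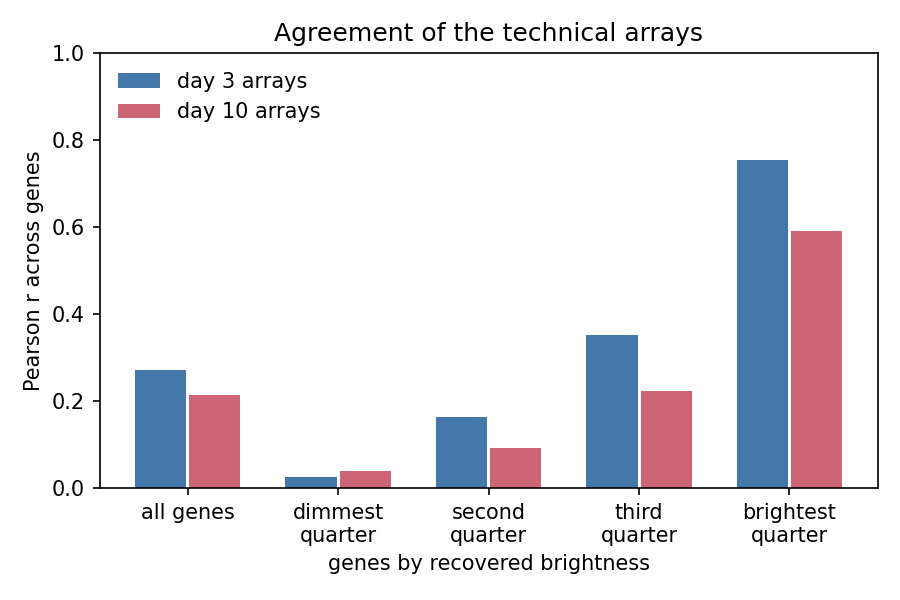
Pearson r across genes between the technical arrays of day 3 (blue) and of day 10 (red), for all genes and for 4 equal sets of genes by recovered brightness. The bars rise from 0.0258 and 0.0394 in the dimmest set to 0.755 and 0.592 in the brightest.

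The first comparison sets day 3 against day 0, early in embryoid body formation. Genes of the ribosome lay on the positive side: 29 of 65 measured ribosomal protein genes were beyond 2-fold there on both arrays and none on the negative side. Rpl22l1 had a log2 ratio of 3.10 ± 0.29 (mean ± SD of 2 technical arrays, as for all gene values here), Rps12 2.42 ± 0.04 and Rpl39 2.39 ± 0.28. Ptma, which encodes prothymosin alpha, had 2.79 ± 0.07, and Ppia, which encodes the prolyl isomerase cyclophilin A, 2.59 ± 0.04. On the negative side stood the pluripotency-associated gene Dppa5a at -2.71 ± 0.04, and Zfp296, another gene of that list, at -2.15 ± 0.67.

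In all, 384 of 13707 genes were beyond 2-fold on both day 3 arrays, 243 on the positive and 141 on the negative side. Another 102 genes were beyond 2-fold with opposite signs on the arrays, a measure of error that equals 26.6% of the called number. In the brightest 25% 142 genes were called and 2 had opposite signs. Besides those above, the genes farthest on the positive side were Egfl7 at 2.76 ± 0.31, a secreted factor of endothelial cells, Papola at 2.74 ± 0.69, the nuclear poly(A) polymerase, and Mettl27 at 2.46 ± 0.81. Farthest on the negative side were Cd3e, Eef1a1-ps1 at -3.45 ± 0.37, Mrps18a at -2.90 ± 0.99, Eef1a1 at -2.54 ± 0.08, Fbxo24 at -2.52 ± 0.31, Cfb at -2.48 ± 1.11 and Zdhhc8 at -2.43 ± 0.68. The value of Cd3e, -5.03 ± 3.90, rests on readings of -7.79 and -2.27. Eef1a1, a translation elongation factor gene, and its pseudogene Eef1a1-ps1 are near-identical copies that spots can share, so their values are uncertain, as are those of ribosomal protein genes with pseudogene copies.

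The ribosomal protein list had a median of 0.79 at day 3, above all 10000 random lists of its size. Glycolysis genes had a median of -0.53 over 15 members (percentile 0.010), with Pgk1, phosphoglycerate kinase, beyond 2-fold at -1.08 ± 0.11. Gapdh, a member of that list with 464 spots, had spot medians of -0.83 and -0.77 on the day 3 arrays and -0.58 and -0.43 on the day 10 arrays. Taking the spot with the smallest array difference brought the glycolysis median inside the central 95% of random lists. The pluripotency list had a median of -0.30 over 31 members (percentile 0.23), with 3 members beyond 2-fold on the negative side and none on the positive. Its best known members did not pass the limit: Pou5f1 was at -0.89 ± 0.15, Zfp42 at -0.78 ± 0.01, Nanog at -0.48 ± 0.37 and Sox2 at -0.38 ± 0.31.

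Smooth muscle and contractile genes had a median of 0.45 over 16 members (percentile 99.8), although their medians on the separate arrays were 0.07 and 0.35, and 1 member, Vcl (vinculin) at 1.43 ± 0.53, was beyond 2-fold. This list fell inside the central 95% without replicate 2 and with the spot of smallest array difference. Primitive streak and mesendoderm genes had a median of 0.29 over 19 members (percentile 97.8), with Mesp1, a transcription factor of early mesoderm, at 1.97 ± 0.10. That list fell inside the range without replicate 1 and with matched random lists.

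The remaining 19 lists lay inside the central 95% at day 3. Single members beyond 2-fold were found in many of them: Dnmt3b, a de novo DNA methyltransferase, at 1.32 ± 0.36, Tie1, an endothelial receptor, at 1.72 ± 0.36, Slc4a1 at 1.44 ± 0.34, Apob at 1.29 ± 0.35, Neurog2 at 1.22 ± 0.19, Timp1 at 1.14 ± 0.15 and Plagl1 at 1.70 ± 0.00. On the other side were Tnnc1, a troponin gene, at -1.11 ± 0.10, Mapt at -1.04 ± 0.05, Hoxa9 at -1.39 ± 0.35, Cox6b1 at -1.37 ± 0.04 and Atp5a1 at -1.28 ± 0.06, while Cox7a2, another called oxidative phosphorylation gene, given after its value was seen, was on the positive side at 1.22 ± 0.21. Hspe1, the mitochondrial chaperonin partner, was at 2.06 ± 0.05 and the inducible chaperone gene Hspa1a at 1.10 ± 0.01. Apob, Slc4a1 and Cox6b1 were in the dimmest 25%, with brightness percentiles of 5.26, 19.9 and 24.7. Of the lists for other cell types, macrophage and leukocyte genes had a median of -0.30 (percentile 2.75) while both array medians were positive at 0.04 and 0.07, and fibroblast feeder and skeletal muscle genes -0.21 (percentile 7.31). Trophoblast genes had 0.12, with Tfap2c at 1.45 ± 0.00, and germ cell genes -0.17, with Prdm1 at -1.08 ± 0.02.

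Other list medians at day 3 were 0.05 for LIF and Stat3 signalling, 0.27 for primed epiblast, 0.05 for extraembryonic endoderm, 0.21 for erythroid genes, 0.03 for endothelium, 0.11 for neural genes and -0.02 for extracellular matrix. Hox genes had 0.05, imprinted genes 0.14, mitosis and replication genes 0.06, cyclin-dependent kinase inhibitors and p53 targets -0.02, BMP, TGF-beta and Wnt targets 0.06, oxidative phosphorylation 0.11 and heat shock and metallothionein genes -0.13. Cardiac muscle genes had a median of -0.08, although both array medians were positive at 0.02 and 0.10. Of the lineage markers followed throughout, Afp was at -0.17 ± 0.20, Actc1 at -0.38 ± 0.16, Myh6 at -0.43 ± 0.09 and Col1a1 at 0.08 ± 0.13.

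**Figure D2:**
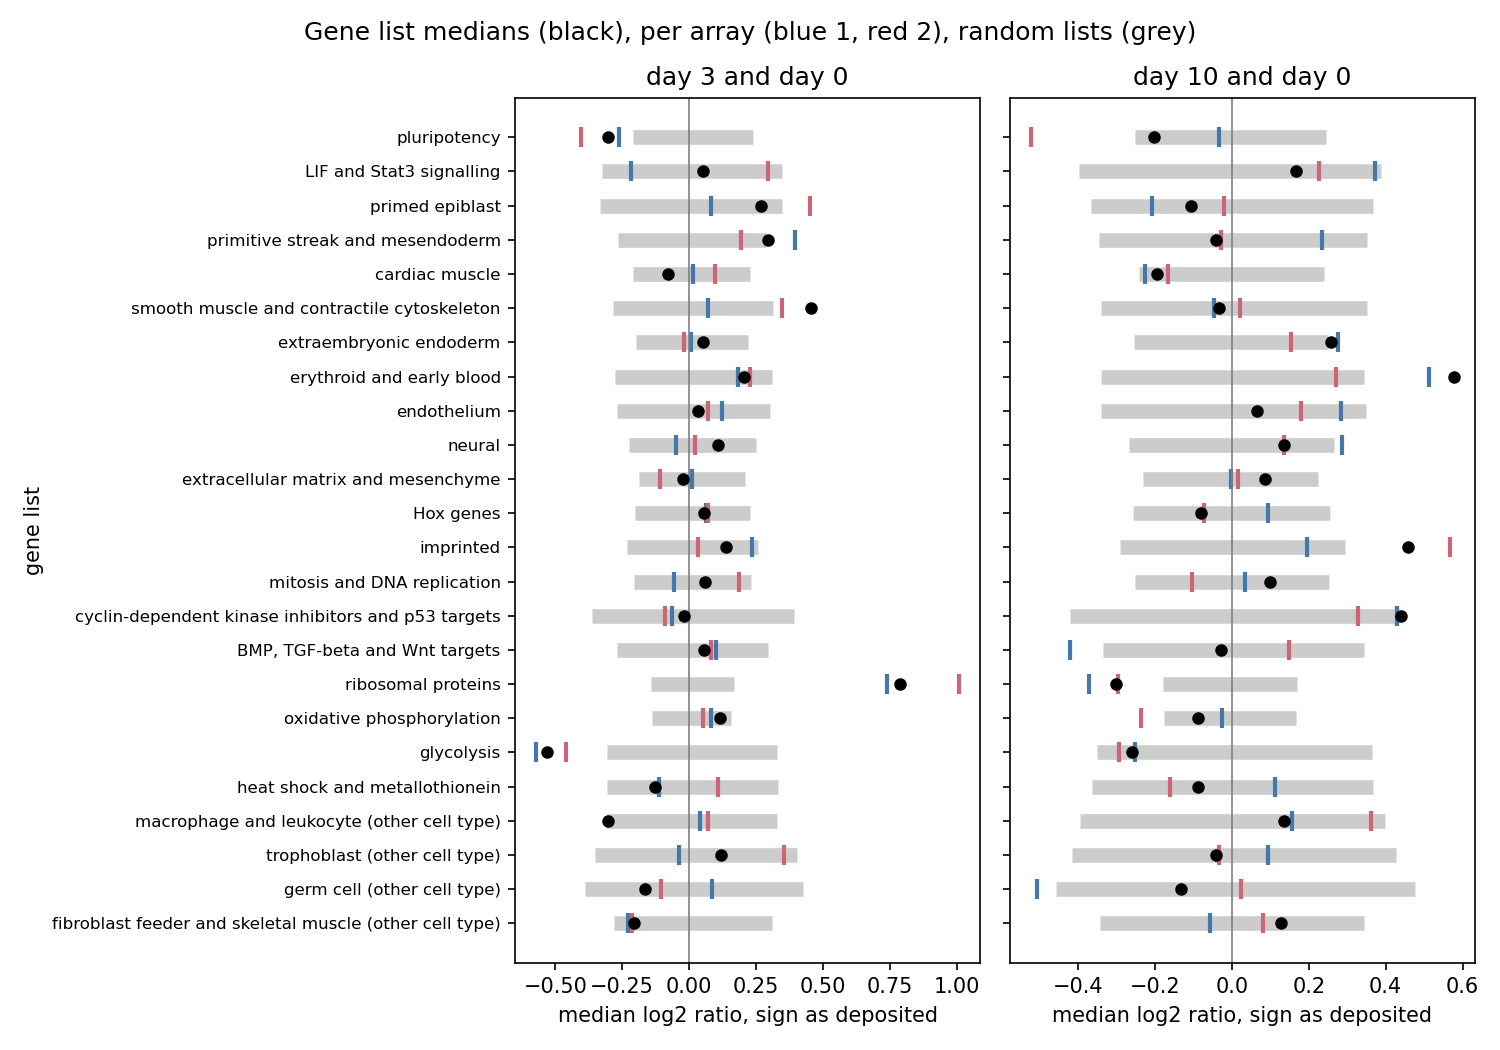
Median log2 ratio, sign as deposited, of each gene list at day 3 (left) and at day 10 (right), as the median over genes of the 2-array mean (black points) and on replicate 1 (blue marks) and replicate 2 (red marks), with the central 95% of 10000 random lists (grey bars). Ribosomal protein genes stand at 0.79 at day 3 and at -0.30 at day 10, outside the grey bar on both sides.

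The second comparison sets day 10 against day 0, a stage when embryoid bodies hold several lineages. Erythroid and early blood genes lay on the positive side with a median of 0.58 over 17 members (percentile 99.9), but of 0.26 without replicate 1 and 0.24 without replicate 2 (percentiles 90.6 and 88.8), both inside the central 95%. The erythropoietin receptor gene Epor at 1.29 ± 0.16 and the heme synthesis gene Alas2 at 1.23 ± 0.23 were beyond 2-fold. Imprinted genes had a median of 0.46 over 22 members (percentile 99.9), but of 0.08 without replicate 2 (percentile 70.3), inside the central range, and 0.65 without replicate 1. Impact was at 1.87 ± 0.94, while the growth factor gene Igf2 was at -1.94 ± 0.45. Ribosomal protein genes had a median of -0.30 over 65 members (percentile 0.020), opposite in sign to day 3, and none was beyond 2-fold. Ferritin heavy chain, an iron storage protein encoded by Fth1, was at 3.28 ± 0.40.

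In all, 467 of 13199 genes were beyond 2-fold on both day 10 arrays, 284 on the positive and 183 on the negative side. Another 195 genes were beyond 2-fold with opposite signs, which equals 41.8% of the called number. In the brightest 25% 139 genes were called, 65 positive and 74 negative, and 4 had opposite signs. In the dimmest 25%, 138 were called and 105 had opposite signs, and at day 3 these numbers were 91 and 64. The genes farthest on the positive side were Pcgf1 at 3.67 ± 0.05, Kif19a at 3.56 ± 2.65, Papola at 3.18 ± 1.85, Hic2 at 3.09 ± 0.75, Slc22a4 at 3.04 ± 0.24 and Daw1 at 2.99 ± 0.38. Fth1 and its pseudogene Fth-ps3, at 3.11 ± 0.57, are near-identical copies and their values are uncertain. Eef1a1 at -3.57 ± 0.14 and Eef1a1-ps1 at -2.78 ± 0.69 were farthest on the negative side, followed by Cabp1 at -2.48 ± 0.10, Nsmce3 at -2.40 ± 1.08, Psph at -2.38 ± 1.28, Dapp1 at -2.36 ± 1.70, Smr3a at -2.30 ± 1.34 and Jade1 at -2.28 ± 0.02. Several of the genes named at day 10 were dim: the brightness percentile was 10.4 for Pcgf1, 2.60 for Hic2, 5.91 for Cited1, 5.21 for Krt19, 2.12 for Hoxc5, 0.820 for Smr3a and 6.99 for Jade1.

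The erythroid list also fell inside the central 95% when the spot with the smallest array difference was taken, and Epor and Alas2 had brightness percentiles of 5.35 and 8.68. The imprinted list, too, fell inside it with that choice of spot, and the ribosomal protein list in the brightest 25% of genes (percentile 6.31). Extraembryonic endoderm genes had a median of 0.26 over 31 members (percentile 97.7), with Cited1 at 1.93 ± 0.61 and the keratin gene Krt19 at 1.43 ± 0.44. The list median was 0.13 without replicate 2, and -0.49 over the 3 members in the brightest 25% of genes. Cyclin-dependent kinase inhibitors and p53 targets had 0.44 over 11 members (percentile 97.6), none of them beyond 2-fold. Both of these lists fell inside the range without either array and with matched random lists.

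The pluripotency list had a median of -0.20 at day 10 (percentile 5.54), inside the central range, with no member beyond 2-fold. It was -0.52 (percentile 0.030, outside the range) without replicate 1 and -0.03 without replicate 2. Pou5f1 was at -1.39 ± 0.99, Zfp42 at -0.55 ± 0.18 and Nanog at -0.22 ± 0.52. Sox2 had a value on 1 array. Afp, a marker of visceral endoderm, was at -0.76 ± 0.84, the cardiac genes Actc1 at -0.37 ± 0.01 and Myh6 at 0.16 ± 0.14, the collagen gene Col1a1 at -0.18 ± 0.62 and the embryonic globin gene Hbb-y at 0.94 ± 0.50, none beyond the limit on both arrays. Among the members of other lists that were beyond it were Egfl7 at 1.57 ± 0.77 and Cldn5, a tight junction gene of endothelium, at 1.37 ± 0.32, Igfbp7 at 1.98 ± 0.60, Tagln2 at 1.34 ± 0.19, Actn1 at 1.16 ± 0.21, Hoxc5 at 1.48 ± 0.60, the mitotic kinase gene Cdk1, with 1.77 and 1.23 on its arrays, and Cenpf at 1.22 ± 0.10. Tk1, a thymidine kinase gene of the mitosis and replication list, was on the other side at -1.13 ± 0.10, and the endothelial gene Plvap was at 1.28 ± 0.14, both given after their values were seen. Ndufa13 was at -1.29 ± 0.28, the metallothionein gene Mt1 at -1.23 ± 0.17, Psg17 at 1.19 ± 0.08 and Myf6 at -1.29 ± 0.25.

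The remaining lists lay inside the central 95% at day 10. Their medians were 0.17 for LIF and Stat3 signalling, -0.11 for primed epiblast, -0.04 for primitive streak, -0.20 for cardiac muscle, -0.03 for smooth muscle, 0.07 for endothelium, 0.14 for neural genes, 0.09 for extracellular matrix and -0.08 for Hox genes. Mitosis and replication genes had 0.10, BMP, TGF-beta and Wnt targets -0.03, oxidative phosphorylation -0.09, glycolysis -0.26 and heat shock and metallothionein genes -0.09. Of the lists for other cell types, macrophage and leukocyte genes had 0.14, trophoblast genes -0.04, germ cell genes -0.13 and fibroblast feeder and skeletal muscle genes 0.13. Some signs turned with an array left out, inside the central 95%. Without replicate 1 and without replicate 2, germ cell genes had 0.25 and -0.51. Fibroblast feeder and skeletal muscle genes had -0.02 and -0.06, and BMP, TGF-beta and Wnt targets 0.21 and -0.33.

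Over both days and the difference between them, 12 of 72 list medians lay outside the central 95%, where 3.6 would by chance. The 3.6 holds for genes drawn at random. If the members of a list vary together, more lists would lie outside with no shift. The 12 are not independent results, since the differences come from the values of both days. Ribosomal proteins count at both days and between them, and imprinted genes at day 10 and between the days. The percentiles describe these RNA samples alone.

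The third comparison sets day 10 against day 3 through the day 0 RNA. That RNA is taken as common to all arrays, which the labels do not state. Ribosomal protein genes had the median difference farthest from 0 of the 24 lists: the difference, day 10 minus day 3, was -1.33 over 63 members, below all 10000 random lists, and 31 members were beyond 2-fold on the negative side in every pair of arrays. Ptma differed by -4.26 ± 0.54, Rpl22l1 by -3.82 ± 0.43, Ppia by -3.21 ± 0.24, Cabp1 by -3.18 ± 0.93 and Hspe1 by -3.13 ± 0.48. On the positive side, Cd3e differed by 4.09 ± 3.90, Pcgf1 by 3.43 ± 0.37, Slc22a4 by 3.21 ± 0.48, Kif19a by 3.09 ± 2.65 and Map1lc3b, an autophagosome protein gene, by 3.08 ± 1.74. Imprinted genes had a median difference of 0.33 over 22 members (percentile 98.4), inside the central range without day 3 replicate 2, without either day 10 array, or with the spot of smallest array difference.

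In all, 448 of 12654 genes with values on the 4 arrays were called, 230 on the positive and 218 on the negative side. In the brightest 25% the split was 55 positive and 85 negative. The other 22 lists lay inside the central 95%, and the nearest to its bounds were extraembryonic endoderm at 0.27 (percentile 97.3, but -0.02 without day 10 replicate 2), macrophage and leukocyte genes at 0.40 (percentile 97.0) and primed epiblast at -0.41 (percentile 3.98). The macrophage and leukocyte list had 0.06 without day 3 replicate 2 and 0.67 (percentile 99.8, outside the range) without day 10 replicate 1. Primed epiblast had -0.74 (percentile 0.04, outside the range) without day 3 replicate 1 and -0.26 without day 3 replicate 2. The pluripotency list had 0.19, but -0.13 without day 10 replicate 1.

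The day 3 and day 10 ratios were also set against each other. Eef1a1, Fbxo24 and Myf6 were beyond 2-fold on the negative side at both days, and Egfl7, Papola and Fth-ps3 on the positive side. In all, 26 genes were negative at both days and 8 positive at both, where independent lists would have 1.85 and 4.55 in common, and 3 genes (4930513L16Rik, Apoc3 and Ptma, of which the first 2 are named because the count is small) changed sides. Across 12654 genes, r between the 2 means was 0.209 (rho 0.226) and the covariance 0.0758. Both ratios have the day 0 RNA in common. In simulated sets, day 0, day 3 and day 10 each had an independent deviation of equal size, with the one of day 0 in common. That size was set from the covariance of the technical arrays at each day, so the data fixed the simulated covariance in advance. Its mean was 0.0717 (range 0.0639 to 0.0811). On average 5.51 genes were negative at both days (2 to 14) and 5.69 positive at both (1 to 12). The observed covariance lies within the simulated range and 0.00412 above its mean, while the 26 genes negative at both days lie above theirs. The covariance cannot tell how much comes from day 0, because the simulation gave all days deviations of equal size. Part of the overlap may come from the day 0 RNA, if it was common to the arrays.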

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

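Of the tests in this part, the ones on brightness used a measure chosen after the data were examined, and the ones on a dye or probe bias of each gene were chosen after the values were seen. The genes and lists given here lay on 1 side on both day 3 arrays and on the other side on both day 10 arrays. That difference was not tested, since each day is 1 RNA sample.

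Among genes, the difference, day 10 minus day 3, was -3.82 for Rpl22l1, -4.26 for Ptma, -3.21 for Ppia, -2.55 for Mettl27, -1.98 for Tie1, -3.13 for Hspe1 and -3.18 for Cabp1. It was 0.59 for Myh6, 1.55 for Cldn5, 1.97 for Impact, 1.87 for Cdk1 and 3.08 for Map1lc3b. Among lists, the difference of the medians was -1.09 for ribosomal proteins, -0.37 for primed epiblast, -0.12 for cardiac muscle, 0.46 for cyclin-dependent kinase inhibitors and p53 targets, and -0.20 for oxidative phosphorylation. For cardiac muscle the arrays changed sides, while the median of the gene means was negative at both days. Some of these sides rest on values near 0 and show no clear turn. Mettl27 had -0.02 and -0.16 on the day 10 arrays, where the SD of 1 array was 0.73 over all genes. Primed epiblast had -0.02 on day 10 replicate 2, oxidative phosphorylation -0.02 on day 10 replicate 1 and cardiac muscle 0.02 on day 3 replicate 1.

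Ribosomal protein genes stood at a median of 0.79 at day 3 and -0.30 at day 10. A dye bias that depends on brightness is argued against: the day 3 median was at percentile 100 and the day 10 median at percentile 1.32 among random lists matched on brightness. With 1 dye orientation at both days, a fixed dye or probe bias of each gene would leave the same value at both, but the median difference over 63 members was -1.33, and between -1.54 and -1.20 over the 4 pairs of arrays. Dyes are not stated, and a swap between the days would turn a dye bias of equal size, but the median sum of the day 3 and day 10 values was 0.77 (0.71 to 0.98 over the pairs) where such a bias gives 0. What stays open is a change in the RNA of these genes between the days and a swapped dye bias that differed in size between labellings. For the day 10 median, a dye bias that depends on brightness stays open as well. A difference in preparation, labelling or array batch between the 2 RNA samples, their day 0 RNA or their hybridisations also stays open. The design places such a difference on the same side as the day.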

How the results depend on the processing

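Centring, a common spread for all arrays, removal of the brightness trend (added after the data were examined) and genes with values on all 4 arrays kept the 3 counts of called genes within 1.5 times. Other choices moved them. At day 3 the count of 384 became 1598 at 1.5-fold, 24 at 4-fold, 1092 with the limit on the mean alone and 991 with each spot on its own, and 142 in the brightest 25% (added later). At day 10 the count of 467 became 1842, 29, 1405, 1135 and 139 under those choices, and between days the count of 448 became 1302, 45, 2052, 876 and 140. Wider or narrower limits move these counts by construction. More units and fewer genes move them too, but do not account for them in full, since the share called also rose. At day 3, 991 of 25981 spots were called, against 384 of 13707 genes. In the brightest 25% the share was 4.09% at day 3, against 2.80% over all genes. At day 10 it was 3.95% against 3.54%, and between days 4.10% against 3.54%.

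Leaving out an array leaves the limit on a single one, which raised the counts by construction. Day 3 had 1797 genes without replicate 1 and 2006 without replicate 2, and day 10 had 2252 and 2776. Between days the count was 1298 and 1448 without the day 3 arrays and 1588 and 2012 without the day 10 arrays. Positive calls were 60.8% of the total at day 10 and 46.8% in the brightest 25%, and between days 51.3% and 39.3%. The cause was not tested.

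The number of lists outside the central 95%, 12 of 72, was 7 with the spot of smallest array difference and 7 of 36 in the brightest 25%, where fewer genes enter, and between 8 and 13 with an array left out. Of the 12, the ribosomal proteins at day 3 and between days and the pluripotency list at day 3 stayed outside under every alternative run. No list outside that range changed the sign of its median where at least 4 members entered. Extraembryonic endoderm at day 10 had 3 members in the brightest 25%, with a median of -0.49. The agreement of the arrays was 0.335 and 0.261 by ranks. In 4 equal sets from dim to bright it was 0.0258, 0.165, 0.351 and 0.755 at day 3, and 0.0394, 0.0935, 0.224 and 0.592 at day 10. Signal over background is not given in the sources used here, so what it limits was not tested. The correlation of day 3 and day 10, 0.209, was 0.289 in the genes with the smaller array differences, 0.359 in the brightest 25% and between 0.151 and 0.185 with an array left out. The cause of these last changes was not tested.

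Of the values of named genes under the alternatives, 533 moved by less than 1 SD of the arrays and 61 by more, and no called gene changed sign. With an array left out, a gene's value moves by less than 1 SD and a called gene keeps its sign by construction. A common spread also keeps that sign. These outcomes are therefore no measure of stability for those alternatives. Of the list medians, 515 moved by less than 1 SD of the arrays and 145 by more. Matching the random lists on array difference or on brightness leaves a list's median unchanged by construction. Those alternatives count among the 515 and are no measure of the stability of the medians. No paired analysis was possible because the labels give the arrays no replicate numbers.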

Other observations

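The tests in this part on the direction of the ratio and on genes called at both days were written down after the values were seen, although the direction comparison itself was fixed in advance. The test on brightness used a measure chosen later.

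Gene families grouped by the letters of their symbols, a grouping chosen after the data were examined, had 3 of 151 medians at a percentile under 0.05 or above 99.95 at day 3, where 0.151 would by chance, and 1 of 141 at day 10. They were the rpl and rps families at 0.65 and 0.60 and the pdcd family (programmed cell death genes) at -0.61 over 10 genes at day 3 (-0.73 and -0.33 on the separate arrays), and the cadherin family at -0.63 over 15 genes at day 10. The rpl and rps families overlap the ribosomal protein list, so they repeat its result and add no separate support. The chance number, too, holds for genes drawn at random. The cadherin median was -0.43 on day 10 replicate 1 and -0.02 on replicate 2, so that shift is nearly absent on 1 array. Of the cadherins 1 was beyond 2-fold on both arrays, and of the pdcd genes none. Among the 12996 unnamed spots, 339 were beyond 2-fold on both day 3 arrays and 153 had opposite signs. At day 10 these numbers were 533 and 218. The 5 sets of control spots had medians between -0.34 and 0.29 on day 3 replicate 1, between -0.10 and 0.43 on day 3 replicate 2, between 0.03 and 0.85 on day 10 replicate 1 and between -0.71 and 0.53 on day 10 replicate 2.

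Pluripotency genes had negative medians at both days, as a ratio of the later day over day 0 would give, since such genes are lower in differentiated cells. At day 10, the pluripotency median minus the mean of the cardiac, matrix and endoderm medians was -0.25 (percentile 4.27 among random lists), and -0.05 and -0.52 on the separate arrays. It was -0.19 against all other genes, but 0.01 in the brightest 25% (0.30 and -0.27 on the arrays), where 8 pluripotency genes had a median of -0.30 and 3 endoderm genes one of -0.49. At day 3, the second case planned, it was -0.29 (percentile 1.29, outside the central 95%), -0.27 and -0.40 on the arrays and -0.30 in the brightest 25% (percentile 9.60). A dye bias that depends on brightness is argued against at day 3, where the median was at percentile 0.3 among random lists matched on brightness. The day 3 values thus lean to the later day over day 0, which may hold as a hypothesis, while the day 10 values, on which the test was set, leave the direction open. The titles of the day 10 arrays name day 0 first ("day0 vs day10"). Read as the order of the ratio, that runs against the lean, so the direction is not settled.

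The 26 genes negative at both days were more than the 14 reached in any of 100 simulated sets with a day 0 deviation in common, while the covariance of 0.0758 was reached or passed by 13 of them. In the brightest 25% 18 genes were negative and 1 positive at both days, and all 100 simulated covariances were at or above the observed 0.111. The simulation draws that deviation from a normal distribution, so a few genes with large deviations could exceed its counts without exceeding its covariance. It also gives day 0 a deviation of the same size as each later day, set from these data. Its covariances therefore cannot tell what comes from day 0. A day 0 RNA or a dye bias of single genes common to all 4 arrays may give such calls, and so may a change that lasts from day 3 to day 10. These cannot be told apart, because all arrays use day 0 RNA and no dye swap is stated.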
